A study of Mus musculus with 65 samples.

How the data were processed

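Messenger RNA was measured on Affymetrix oligonucleotide arrays in 17 mouse mammary glands and 48 mouse mammary tumours. Per the labels, the glands came from BALB/c littermates that were wild-type or heterozygous for Tgfb1, 10 weeks old, given estrogen and progesterone to align their cycles, and exposed to 10 cGy or to a sham treatment. Glands were taken 1 or 4 weeks later, the lymph node was removed, and RNA came from the posterior part of the inguinal gland. The tumours grew from p53-null mammary tissue placed in fat pads cleared of their own epithelium, in hosts with both copies or 1 copy of Tgfb1 that had been irradiated or sham-treated shortly before. The host dose is not given in the sources used here. Labelling started from 80 ng of RNA for glands and 100 ng for tumours, per the labels.

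The authors deposited gland values as intensity on a linear scale, and per the submitters' processing notes these were made with RMA, which corrects background, normalizes between arrays and summarises the probes of each probe set. The tumour values were deposited as log2 values, also made with RMA per the submitters' processing notes. The version of RMA, and whether both tissues were normalized together, are not given in the sources used here. Gland array medians were 29.08 to 30.56 in deposited intensity, and tumour array medians were 5.84 to 5.96 in deposited log2 units. Gland intensities were converted to log2 here. Because the scales and label protocols differed, no gland was compared with a tumour.

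Each array held 45101 probe sets. The annotation of the platform gave 34958 of them 1 gene, 932 several genes and 9211 no gene, and only the first kind was used. Gene identifiers were looked up in a mouse RefSeq table of assembly GRCm38.p6, where 99.4% matched and 0 symbols changed. That table served only for names and for the order of genes along chromosomes. Each of 18194 genes was represented by its probe set with the highest mean over the arrays of the tissue. Genes whose mean lay under the 40th percentile were set aside, at 4.15 on the log2 scale in glands and 5.14 in tumours, which left 12945 and 12786 genes. Signal over background was not measured per probe in these values, so this percentile was the only guard against dim genes.

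Groups came from the labels. In 1 tumour the labels disagreed on host treatment, and it was placed by its title among tumours of irradiated wild-type hosts. The labels number repeats within groups and give each tumour its own host. Whether gland repeats are separate animals is not stated, so gland p-values may reflect partly technical spread. Whether the numbers pair arrays was checked by correlating their deviations from the group means. All 6 same-numbered pairs of a sham and a 4-week gland were over 0.1 (0.123 to 0.216 in wild-type and 0.112 to 0.316 in heterozygotes). The numbers may thus pair those groups, which the labels do not state. Over all gland groups, differently numbered pairs reached 0.481 in wild-type and 0.282 in heterozygotes, so the pairing is not settled. The main fit did not use it. Pairs with 1-week glands reached down to -0.219 and pairs of tumours to -0.368, so those were not taken as pairs. No arrays were identical. Correlations between arrays of a group were 0.982 to 0.993 in glands and 0.918 to 0.990 in tumours.

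Differences were fitted in R 4.3.3 with limma 3.58.1, in 1 linear model per tissue with a mean for each group and empirical Bayes variances with a trend on mean level, which left 11 residual degrees of freedom in glands and 44 in tumours. All p-values were two-sided and adjusted over the tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. In the main fits chance gives 647 gland and 639 tumour genes an unadjusted p under 0.05, so lower counts are no sign of change. There were 9 gland comparisons and 5 tumour comparisons. The genotype average was the mean of the 3 heterozygote minus wild-type differences (sham, 1 week and 4 weeks). The time comparison was the mean over genotypes of 4 weeks minus 1 week after 10 cGy. An interaction was the change in heterozygotes minus the change in wild-type. Sham glands were taken at 1 week only, so a comparison of 4-week glands with sham glands also spans 3 weeks of age.

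Expression was also summarised over 39 gene lists, 20 of cell-type markers and 19 of pathways. Lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, which covered 38 lists in glands and 36 in tumours. Camera was repeated with a correlation estimated from the residuals of each list, and the rotation test fry was run beside it. Of 342 pairs of a list and a gland comparison, 67 passed camera at the preset correlation, and of 180 tumour pairs 36 passed. With an estimated correlation 0 pairs passed in either tissue, the smallest adjusted p being 0.219 in glands and 0.330 in tumours. With fry 0 pairs passed, the smallest adjusted p being 0.164 and 0.366. A list mean is the mean log2 level of its members on 1 array.

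The groups, tests, gene lists, alternatives and the rule for named genes were set before the data were examined, except where stated. Under that rule, fixed genes were selected where measured, together with up to 10 higher and 10 lower genes past the threshold in each comparison. Where fewer than 6 genes passed, the 3 higher and 3 lower genes with the smallest p were selected too, as genes that did not pass. For each list, up to 4 members past the threshold were selected, or, for a list past camera without such a member, the 2 members with the smallest p in its direction. The text names only part of the genes so selected that did not pass. Unnamed or predicted genes were not named, and 2 of the fixed genes had no named probe set.

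The alternatives were no filter, a stricter filter at the 60th percentile, the mean of probe sets per gene, quantile normalization, median centring, no variance trend, robust variances, array weights, the compared groups alone, the repeat number as a block, list means as covariates (luminal epithelium with B cells and lymph node in glands, and with skeletal muscle in tumours), the doubtful tumour left out or moved to sham, and leaving out each array in turn. Fits with a skeletal muscle covariate, without 4 muscle-rich or 3 lymph-node-rich gland arrays, or with luminal epithelium as the single covariate in tumours were chosen after seeing the data. Leaving out either heterozygous 1-week array leaves 1 array in that group, so the spread in those fits comes from the other groups alone. Likewise the fit without muscle-rich arrays removes wild-type sham arrays 2 and 3, wild-type 1-week array 3 and wild-type 4-week array 3, and keeps a single wild-type sham array. The number of arrays limits the precision of every value. The fits were tested on simulated data with 200 genes changed by 1.5-fold, 2-fold or 4-fold in each comparison. The simulated noise was normal and independent between genes, whereas the arrays hold genes that move together, such as muscle genes. Recovery also depends on 200 genes being changed, so the shares given below may be too high for data with fewer changes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.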

Results

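The gland series comprised 6 groups, with 3 arrays each of wild-type sham, wild-type 1 week after 10 cGy, wild-type 4 weeks after 10 cGy, heterozygous sham and heterozygous 4 weeks after 10 cGy, and 2 arrays of heterozygous glands 1 week after 10 cGy. The tumour series comprised 9 tumours from sham wild-type hosts, 23 from irradiated wild-type hosts, 6 from sham heterozygous hosts and 10 from irradiated heterozygous hosts. The study asked whether a low radiation dose acts on mammary tissue through TGF-beta, a growth inhibitor and regulator of matrix and immunity encoded in part by Tgfb1. Glands lacking 1 copy of Tgfb1, and hosts lacking 1 copy, address that question. Differences are in log2 units with their standard error (SE) from limma, and group levels are means ± SD over arrays.

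Tgfb1 itself was measured in every array. In glands it averaged 5.09 ± 0.05 (n = 3) in wild-type sham, 5.16 ± 0.40 (n = 3) in wild-type at 1 week and 4.93 ± 0.37 (n = 3) in wild-type at 4 weeks. The heterozygous groups averaged 4.41 ± 0.29 (n = 3), 3.83 ± 0.03 (n = 2) and 4.42 ± 0.20 (n = 3). Tgfb1 was thus dim in glands, near or under the array medians of 4.86 to 4.93 in log2 units. The heterozygous 1-week mean lay under the filter level of 4.15, which was applied to the mean over all glands. Averaged over conditions, Tgfb1 was lower in heterozygotes by a difference of -0.84 (SE 0.13), with a limma adjusted p = 0.0351, and 6 of 8 heterozygous glands lay below all 9 wild-type glands. A second, dimmer Tgfb1 probe set with a mean level of 3.89 differed by -0.02, and with the mean of probe sets Tgfb1 was at -0.43 and missed the threshold (limma adjusted p = 0.0625). It also missed it with the repeat number as a block (-0.82, limma adjusted p = 0.0574). Which part of the gene was deleted is not given in the sources used here, so the probe sets may lie outside it. In tumours, which can hold host cells beside the donor epithelium, Tgfb1 averaged 9.18 ± 0.91 (n = 9) and 8.75 ± 0.41 (n = 23) in sham and irradiated wild-type hosts, and 8.23 ± 0.94 (n = 6) and 8.53 ± 0.34 (n = 10) in sham and irradiated heterozygous hosts.

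Heterozygous and wild-type glands, averaged over sham, 1 week and 4 weeks, differed in 6 genes. Tyw5, an enzyme that modifies transfer RNA, rose by 0.60 (SE 0.07), and Maip1, a mitochondrial matrix protein, rose by 0.65 (SE 0.09). Prr32 rose by 1.07 (SE 0.15). Lower in heterozygotes were Tgfb1, the histone gene H2bc18 at -0.54 (SE 0.07) and Capn6, a calpain family member, at -0.73 (SE 0.12). Dimmer second probe sets of Maip1 and Capn6, at mean levels of 3.11 and 3.86, differed by 0.09 and -0.06. With the mean of probe sets Maip1 was at 0.37 and passed (limma adjusted p = 0.0245), and Capn6 was at -0.39 and did not (0.152). For Tyw5, Maip1, Prr32 and H2bc18, 8 of 8 heterozygous glands lay outside the range of the 9 wild-type glands, and for Capn6 5 of 8 did. Limma's adjusted p was 0.0102 for Tyw5, 0.0142 for Maip1 and for H2bc18, 0.0150 for Prr32 and 0.0401 for Capn6, and 1559 of 12945 genes had an unadjusted p under 0.05, where 647 were expected by chance. In the simulated data this comparison recovered 74.6% of 1.5-fold, 94.0% of 2-fold and 97.0% of 4-fold changes. Tyw5 and Maip1 passed in each of the 17 fits without 1 array. H2bc18 missed the threshold without heterozygous 1-week array 2 (adjusted p = 0.0567), Prr32 without heterozygous 1-week array 1 (0.0587), Tgfb1 in 8 of the 17 fits (up to 0.150, without heterozygous 1-week array 2) and Capn6 in 12 of them (up to 0.137). Capn6 also missed it with quantile normalization, composition covariates, a muscle covariate or the repeat number as a block (-0.73, limma adjusted p = 0.0732 with the block). The count itself ran from 3, without heterozygous 1-week array 2, to 15, without heterozygous sham array 2. Without the 3 lymph-node-rich arrays 0 genes passed limma, with 1707 at an unadjusted p under 0.05, and Tyw5 was then at 0.64 and Maip1 at 0.68, both with an adjusted p of 0.0535. Without the 4 muscle-rich arrays, a fit with 1 wild-type sham array, none of these 6 genes passed limma, with Tyw5 at 0.56 and Maip1 at 0.57 (both adjusted p = 0.199), while 1 other gene did and 935 had an unadjusted p under 0.05.

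**Figure D1:**
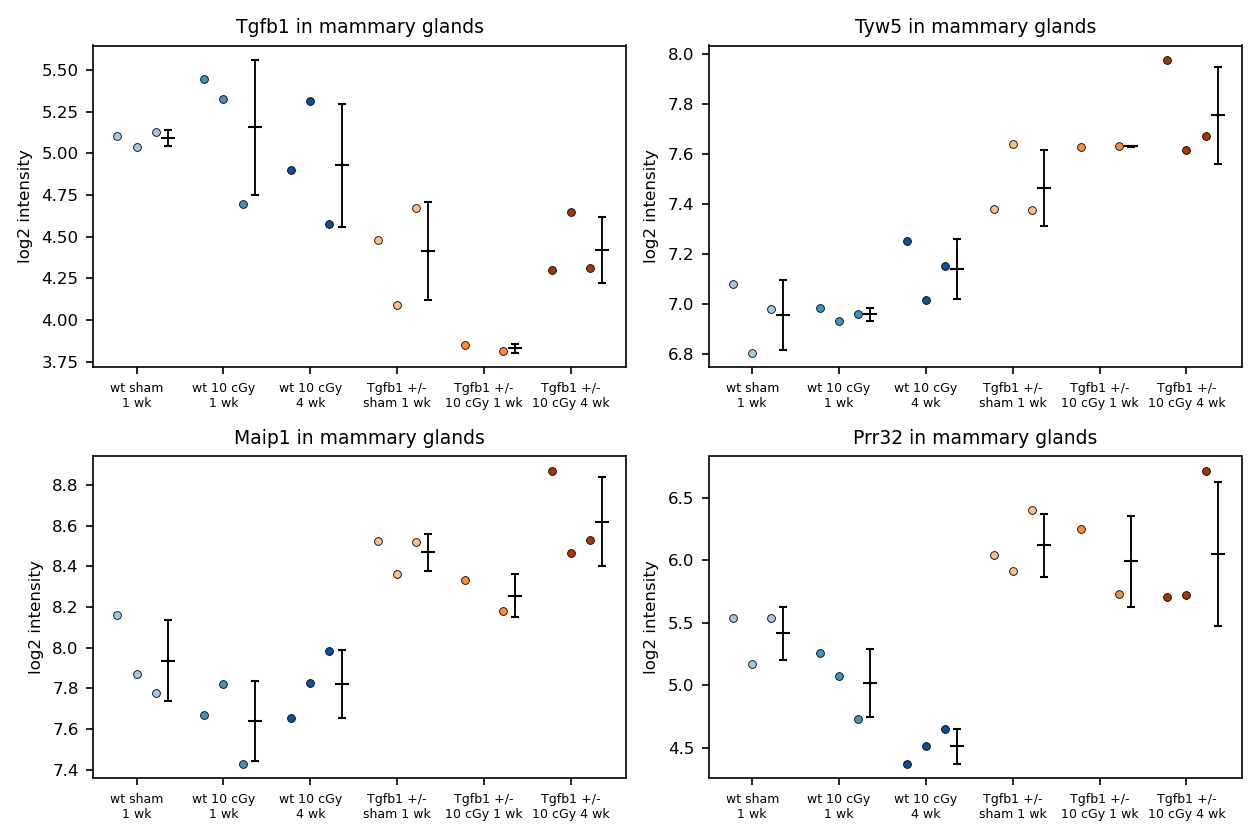
Log2 intensity of Tgfb1, Tyw5, Maip1 and Prr32 in each mammary gland array (points) by group, with bars for the mean ± SD, wt being wild-type and wk weeks after treatment. For Tyw5, Maip1 and Prr32 all 8 heterozygous arrays lie above all 9 wild-type arrays, and for Tgfb1 6 of 8 lie below them.

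Collagen and fibroblast genes were lower in heterozygous glands, and cell-cycle genes were higher. Of 17 fibroblast and collagen genes 16 were lower, with a mean of -0.19 and a camera adjusted p = 0.000273 (adjusted p = 0.729 with an estimated correlation). None passed limma over all genes, 8 had an unadjusted p under 0.05 and 8 passed when adjusted over the list alone, among them Col1a1 at -0.50 (SE 0.10) and Col1a2 at -0.26 (SE 0.06), the chains of type I collagen. All 23 proliferation genes were higher on average over conditions, with a mean of 0.40 and a camera adjusted p = 0.000151 (adjusted p = 0.729 with an estimated correlation). The list mean was higher in heterozygotes in sham (8.15 against 7.48) and at 1 week (8.30 against 7.56) but lower at 4 weeks (7.93 against 8.14). The proliferation mean fell to 0.22 without wild-type sham array 2 (camera adjusted p = 0.0178), and to 0.27 without wild-type 1-week array 1 (0.00312) or heterozygous sham array 3 (0.00369). Mcm5, a subunit of the replicative helicase, was at 0.60 (SE 0.26) and Pcna, the replication clamp, at 0.46 (SE 0.17), and 0 of the 23 passed limma, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. Neutrophil genes were higher in 5 of 6 cases, with a mean of 0.29, a camera adjusted p = 0.0116 and an adjusted p = 0.669 with an estimated correlation. They were led by the gelatinase gene Mmp9 at 0.88 (SE 0.16), which passed when adjusted over the list alone and not over all genes (limma adjusted p = 0.0596). These 3 lists passed camera in every fit without 1 array, whereas 7 further lists that passed did not. Skeletal muscle markers moved with these groups, since their list mean was 7.95 ± 3.48 in wild-type sham glands and 5.23 ± 1.51 in heterozygous sham glands (n = 3 each). Without the 4 muscle-rich arrays, which leaves 1 wild-type sham array, the neutrophil mean was 0.17 and the sham proliferation difference turned negative. The proliferation average rests partly on these arrays.

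Among the 7 further lists, TGF-beta pathway components were lower in 11 of 14 genes, with a mean of -0.15, a camera adjusted p = 0.0412 and an adjusted p = 0.669 with an estimated correlation. Tgfb1 was the single member to pass limma over all genes and when adjusted over the list alone, and 10 of the 17 fits without 1 array lost the call (up to an adjusted p of 0.302, without heterozygous 1-week array 1). MHC class II genes, which present antigen, were lower in 9 of 9 cases, with a mean of -0.29, a camera adjusted p = 0.0141 and an adjusted p = 0.729 with an estimated correlation. H2-Ab1 was at -0.31 (SE 0.14). The average came mostly from 1 week, where the list mean was 8.18 in heterozygotes against 9.10, with 8.39 against 8.51 in sham, and at 4 weeks it was higher in heterozygotes, at 8.57, than in wild-type glands. That call was lost without heterozygous 1-week array 1 (0.0731), wild-type 1-week array 1 (0.0551), or wild-type 4-week array 1 (0.0674) or 2 (0.0777).

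In sham glands alone, which show the genotype without radiation, 0 genes passed limma, with 460 at an unadjusted p under 0.05. Tgfb1 was at -0.68 (SE 0.22), Krt4, a keratin of stratified epithelium, at 1.35 (SE 0.27) and Epgn, a ligand of the EGF receptor, at 1.80 (SE 0.40). Proliferation genes were higher in 23 of 23 cases, with a mean of 0.67, a camera adjusted p = 2.48e-06 and an adjusted p = 0.899 with an estimated correlation. Fibroblast and collagen genes were lower in 13 of 17 cases, with a mean of -0.20, a camera adjusted p = 0.000173 and an adjusted p = 0.769 with an estimated correlation. Postn, a matrix protein induced by TGF-beta, was at -0.50 (SE 0.15). Skeletal muscle genes were lower in 16 of 16 cases, with a mean of -2.72, a camera adjusted p = 6.11e-07 and an adjusted p = 0.769 with an estimated correlation. No member of these 3 lists passed limma over all genes or when adjusted over the list alone, and at an unadjusted p under 0.05 there were 6 fibroblast genes and 0 of the other lists. Wild-type sham array 2 combined the highest muscle list mean of all glands, 11.12, with the lowest proliferation mean of its group, 6.37. Without it the proliferation mean was 0.12 (camera adjusted p = 0.574), the muscle mean -1.14 (0.109) and the fibroblast mean -0.08 (0.170). Without heterozygous sham array 3 the fibroblast mean was -0.13 (0.0527) and the proliferation mean 0.27 (0.0410). Leaving out wild-type sham array 1 gave 1.19 for proliferation and -4.59 for muscle, and leaving out heterozygous sham array 1 gave 1.02 for proliferation. Without the 4 muscle-rich arrays proliferation was at -0.35 and muscle at 1.08, against wild-type sham array 1 alone. Of 8 lists past camera in this comparison none passed in every fit without 1 array. Simulated changes were recovered at 43.3% for 1.5-fold, 70.1% for 2-fold and 97.0% for 4-fold.

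At 1 week after 10 cGy, wild-type glands had higher levels of MHC class II, interferon and macrophage genes than sham glands, while the lists of B cells and lymph node, T and NK cells and neutrophils did not pass camera (adjusted p = 0.118, 0.136 and 0.194). All 9 MHC class II genes were higher, with a mean of 0.59, a camera adjusted p = 1.07e-07 and an adjusted p = 0.572 with an estimated correlation. H2-Eb1 was at 0.66 (SE 0.26) and H2-DMa, which loads peptides on class II molecules, at 0.59 (SE 0.22). The list mean was 9.10 ± 0.43 (n = 3) after 10 cGy and 8.51 ± 0.29 (n = 3) after sham, and each of the 3 irradiated arrays lay above each sham array. Genes of the interferon gamma response were higher in 12 of 13 cases, with a mean of 0.30, a camera adjusted p = 1.01e-05 and an adjusted p = 0.572 with an estimated correlation. Igtp, an interferon-induced GTPase, was at 0.54 (SE 0.19) and Psmb9, an immunoproteasome subunit, at 0.47 (SE 0.16). No member of either list passed limma over all genes or when adjusted over the list alone, while 5 of each list had an unadjusted p under 0.05. Both lists passed camera in every fit without 1 array, but their size rested on single arrays. Leaving out wild-type 1-week array 1 lowered the MHC class II mean to 0.34 (camera adjusted p = 0.00610) and the interferon gamma mean to 0.18 (0.00513), and leaving out wild-type sham array 1 lowered the latter to 0.16 (0.00182). Lymph-node and muscle markers moved with them, as the B cell and lymph node list mean was 6.83 ± 2.38 after 10 cGy (9.58 in array 1) and 6.27 ± 0.99 after sham, and the skeletal muscle mean was 5.78 ± 2.78 against 7.95 ± 3.48.

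Markers of macrophages were higher in 13 of 14 cases, with a mean of 0.42, a camera adjusted p = 8.90e-05 and an adjusted p = 0.637 with an estimated correlation. Lyz2, a lysozyme of myeloid cells, was at 0.72 (SE 0.28), and without wild-type 1-week array 2 the mean fell to 0.15 (camera adjusted p = 0.0891). It was 0.27 without wild-type sham array 3 and 0.70 without wild-type 1-week array 1. Type I interferon genes were higher in 13 of 13 cases, with a mean of 0.38, a camera adjusted p = 0.00123 and an adjusted p = 0.637 with an estimated correlation. Without wild-type 1-week array 2 they were at 0.03 (camera adjusted p = 0.587), and without array 1 at 0.82. Milk protein genes were lower in 11 of 12 cases, with a mean of -1.11, a camera adjusted p = 0.0145 and an adjusted p = 0.637 with an estimated correlation. The caseins Csn1s2b and Csn3 were at -3.33 (SE 1.17) and -1.24 (SE 0.51). Cholesterol synthesis genes were lower in 9 of 11 cases, with a mean of -0.24, a camera adjusted p = 0.0145 and an adjusted p = 0.637 with an estimated correlation. Fdft1, squalene synthase, at -0.60 (SE 0.15), passed when adjusted over the list alone and not over all genes. The milk call was lost without wild-type sham array 2 (-0.71, adjusted p = 0.1002) or wild-type 1-week array 1 (-1.11, 0.0646) or 2 (-1.05, 0.111). The cholesterol call was lost without wild-type sham array 1 (-0.07, 0.562) or 3 (-0.21, 0.0797) or wild-type 1-week array 3 (-0.16, 0.0647), and its mean was -0.45 without wild-type sham array 2.

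Skeletal muscle genes were lower in 16 of 16 cases at 1 week, with a mean of -2.17, a camera adjusted p = 0.000327 and an adjusted p = 0.637 with an estimated correlation. Without wild-type sham array 2 they were at -0.58 (0.509), and without wild-type 1-week array 1 at -1.37 (0.0775) or 2 at -1.36 (0.141). They were at -4.03 without wild-type sham array 1 and -3.77 without wild-type 1-week array 3. Luminal epithelium genes were lower in 12 of 14 cases, with a mean of -0.21, a camera adjusted p = 0.0331 and an adjusted p = 0.726 with an estimated correlation, a call lost without wild-type sham array 3 (-0.008, 0.676) or wild-type 1-week array 1 (-0.22, 0.0716) or 2 (-0.17, 0.328). In all, 14 lists passed camera, 2 of them in every fit without 1 array. Of single genes, 0 passed limma (smallest adjusted p = 0.541) and 588 (647 by chance) had an unadjusted p under 0.05. With the smallest p were H2bc18 at 0.71 (SE 0.12), H1f2, a linker histone, at -0.67 (SE 0.13), and Tsc22d3 at 0.84 (SE 0.20) and Per1 at 0.80 (SE 0.22), both glucocorticoid-responsive genes. Cdkn1a, the cell-cycle inhibitor p21 induced by p53 after DNA damage, was at 0.50 (SE 0.14), and Esr1, the estrogen receptor, at -0.40 (SE 0.17), neither passing. In the simulated data, recovery was 44.8% for 1.5-fold, 74.6% for 2-fold and 97.0% for 4-fold. Without the 3 lymph-node-rich arrays 1 gene passed.

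**Figure D2:**
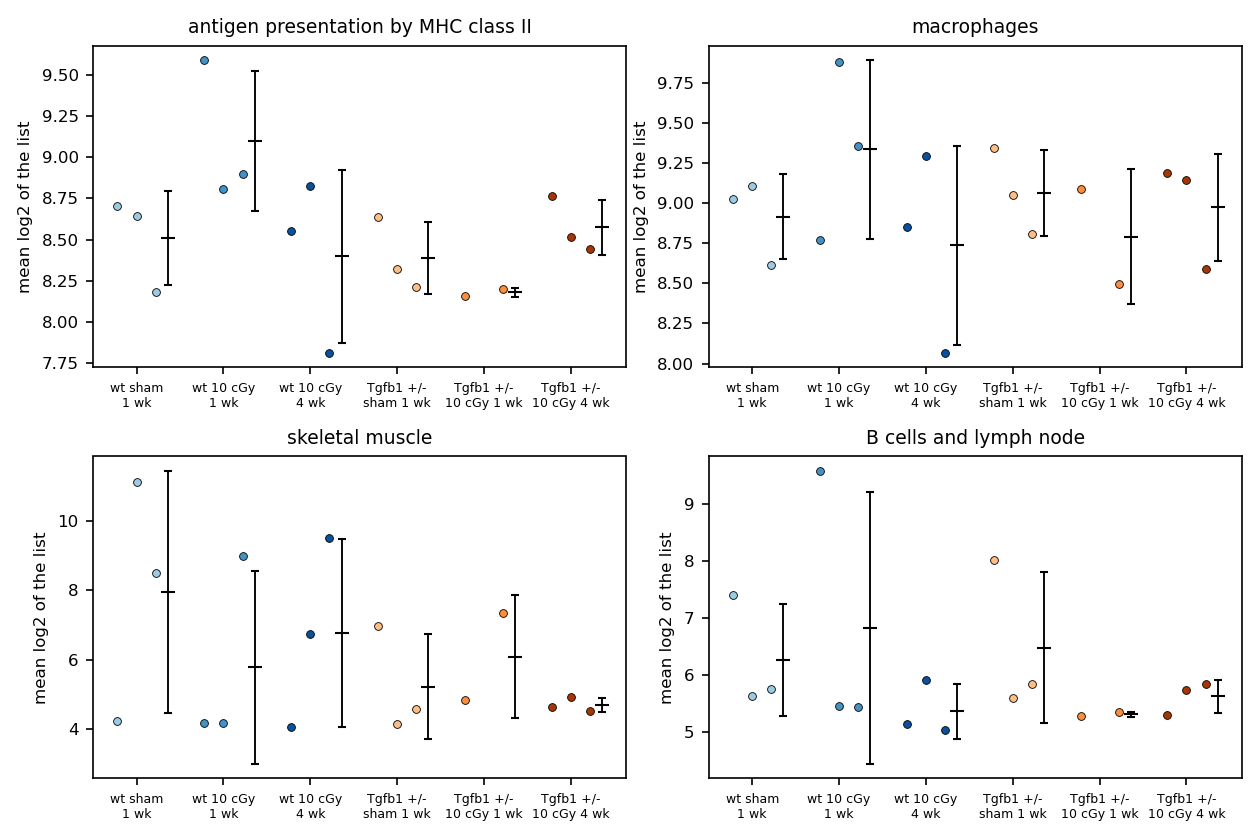
Mean log2 level of the MHC class II, macrophage, skeletal muscle and B cell and lymph node lists in each mammary gland array (points) by group, with bars for the mean ± SD, wt being wild-type and wk weeks after treatment. The MHC class II mean is 9.10 ± 0.43 in wild-type glands at 1 week after 10 cGy, and the muscle and lymph node panels show single arrays far above their groups, such as 11.12 for muscle in wild-type sham and 9.58 for lymph node in wild-type at 1 week.

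At 4 weeks after 10 cGy, wild-type glands had higher basal and myoepithelial markers than sham glands of 1 week. Of 13 such genes 11 were higher, with a mean of 0.33, a camera adjusted p = 6.95e-05 and an adjusted p = 0.219 with an estimated correlation. Acta2, smooth-muscle actin of the contractile layer, was at 0.36 (SE 0.16) and Mylk, its myosin kinase, at 0.46 (SE 0.23). Hypoxia and glycolysis genes were lower in 14 of 14 cases, with a mean of -0.17, a camera adjusted p = 0.000591 and an adjusted p = 0.219 with an estimated correlation. Aldoa, a glycolytic aldolase also abundant in muscle, was at -0.54 (SE 0.21), and the skeletal muscle list itself was at -1.18 with a camera adjusted p = 0.00343 (adjusted p = 0.741 with an estimated correlation). No member of these lists passed limma over all genes or when adjusted over the list alone, with 1 basal, 1 hypoxia and 0 muscle genes at an unadjusted p under 0.05. The basal and hypoxia calls held in every fit without 1 array. Without the 4 muscle-rich arrays the hypoxia mean was -0.02 and the muscle mean 1.30, but that fit keeps a single sham array, number 1. The muscle mean was 0.40 without wild-type sham array 2 (0.936), 0.17 without wild-type 4-week array 1 (0.648) and -0.90 without wild-type sham array 3 (0.103). It was -3.05 without wild-type sham array 1 and -2.54 without wild-type 4-week array 3.

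Proliferation genes were higher in 23 of 23 cases in the same comparison, with a mean of 0.66, a camera adjusted p = 2.51e-05 and an adjusted p = 0.741 with an estimated correlation. Bub1b, a spindle checkpoint kinase, was at 0.89 (SE 0.56) and Mki67, a marker of cycling cells, at 0.85 (SE 0.59). Their mean was 0.11 without wild-type sham array 2 (camera adjusted p = 0.959) and 1.18 without array 1 of that group, without wild-type 4-week array 3 it was 0.35 (0.0951), and without the 4 muscle-rich arrays -0.68 (0.00390), against sham array 1 alone. Neutrophil genes were lower in 6 of 6 cases, with a mean of -0.40, a camera adjusted p = 9.56e-05 and an adjusted p = 0.219 with an estimated correlation. The calprotectin genes S100a8 and S100a9 were at -0.77 (SE 0.29) and -0.79 (SE 0.28), and without wild-type 4-week array 3 the mean was -0.30 (0.0987), and without wild-type sham array 1 it was -0.26 (0.0154). T and NK cell genes and B cell and lymph node genes were lower by means of -0.66 and -0.90, with camera adjusted p-values of 0.00747 and 0.0156 (adjusted p = 0.741 for both with an estimated correlation). Without wild-type sham array 1, whose lymph-node mean was 7.40, they were at -0.24 (0.485) and -0.35 (0.467), and without wild-type 4-week array 3 at -0.50 (0.411) and -0.74 (0.200). Of single genes 0 passed limma and 296 had an unadjusted p under 0.05. Capn6 was at 0.95 (SE 0.19) and Padi2, an enzyme converting arginine to citrulline, at -0.93 (SE 0.23). Simulated changes were recovered at 32.8% for 1.5-fold, 76.1% for 2-fold and 97.0% for 4-fold.

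In heterozygous glands 1 week after 10 cGy, milk protein genes were higher than in sham glands in 11 of 12 cases. Their mean was 1.28, with a camera adjusted p = 5.80e-06 and an adjusted p = 0.999 with an estimated correlation. Csn3 was at 1.32 (SE 0.57), and 0 of the 12 passed limma over all genes or when adjusted over the list alone, with 3 at an unadjusted p under 0.05. The list mean was 11.94 in array 2 and 7.34 in array 1 of this group, against 8.36 ± 0.82 (n = 3) in sham. Without array 2 the difference was -1.02 (camera adjusted p = 0.260), and without array 1 it was 3.58, so the call and its direction rested on that array. Of single genes 0 passed limma, with 513 at an unadjusted p under 0.05. Saa1, an acute-phase protein, was at 3.08 (SE 0.62, limma adjusted p = 0.890) and Ccnc, cyclin C, at -0.59 (SE 0.12). Without heterozygous 1-week array 1, 15 genes passed, but that fit leaves 1 array in the group and takes the spread from other groups alone. In the simulated data, recovery was 25.4% for 1.5-fold, 83.6% for 2-fold and 97.0% for 4-fold, with 2 arrays in the irradiated group.

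In heterozygous glands 4 weeks after 10 cGy, Dusp1, a phosphatase that switches off MAP kinases and an immediate early gene, rose by 1.18 (SE 0.16) over sham glands. Tuba8, an alpha-tubulin, fell by 1.73 (SE 0.25). Dusp1 averaged 10.13 ± 0.04 (n = 3) at 4 weeks and 8.95 ± 0.21 (n = 3) in sham, Tuba8 averaged 5.59 ± 0.28 and 7.32 ± 0.19, and for both genes 3 of 3 irradiated arrays lay outside the range of the sham arrays, as 10% of genes would by chance in either direction. Limma's adjusted p was 0.0387 for Dusp1 and 0.0425 for Tuba8, and 685 genes had an unadjusted p under 0.05. Dusp1 missed the threshold in 10 and Tuba8 in 13 of the 17 fits without 1 array (up to 0.319 for both), and with the compared groups alone 0 genes passed limma, 788 having an unadjusted p under 0.05. The count ran from 0, in 9 of those 17 fits, to 4, without wild-type sham array 2 or 3. A second Tuba8 probe set, at a mean level of 4.85, was at -1.26, and with the mean of probe sets Tuba8 missed the threshold (-1.49, 0.114). With the repeat number, which may pair these groups, as a block, 0 genes passed limma, with 725 at an unadjusted p under 0.05. Dusp1 was then at 1.18 (limma adjusted p = 0.0860) and Tuba8 at -1.73 (0.0932). Both calls also ended, with differences about as large, with composition covariates (1.13 and -1.57, both 0.262) and without the lymph-node-rich arrays (1.11, 0.157, and -1.71, 0.0957). With array weights 14 genes passed limma, 4 higher and 10 lower.

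Luminal epithelium genes were lower in 10 of 14 cases in heterozygous glands at 4 weeks, with a mean of -0.29, a camera adjusted p = 0.00628 and an adjusted p = 0.825 with an estimated correlation. When adjusted over the list alone 4 lower members and 1 higher member passed, and 0 passed limma over all genes, with 6 at an unadjusted p under 0.05 (5 lower, 1 higher). Krt19 and Krt8, keratins of luminal cells, were at -1.28 (SE 0.25) and -0.73 (SE 0.24), and Cldn4, a tight-junction protein, at -1.12 (SE 0.24). Hormone-sensing luminal genes were lower in 6 of 8 cases, with a median of -0.28, a mean of -0.07, a camera adjusted p = 0.0390 and an adjusted p = 0.825 with an estimated correlation. Tbx3, a transcription factor of that lineage, at -0.92 (SE 0.24), passed when adjusted over the list alone, and Pgr, the progesterone receptor, was at -0.79 (SE 0.28). Fibroblast and collagen genes were higher in 13 of 17 cases, with a mean of 0.13, a camera adjusted p = 0.0390 and an adjusted p = 0.825 with an estimated correlation. The luminal call was lost without heterozygous sham array 2 (-0.15, adjusted p = 0.433), and its mean was -0.48 without heterozygous sham array 1. The hormone-sensing mean was 0.26 without heterozygous 4-week array 1 (0.253) and 0.18 without heterozygous sham array 2 (0.276), and that call also missed the threshold in 3 more fits (up to 0.0626). It was -0.21 and -0.17 without heterozygous sham array 1 and 3, and -0.17 and -0.29 without heterozygous 4-week array 2 and 3. The fibroblast call was lost in 6 fits, up to 0.542 without heterozygous sham array 3 (0.055), and with 0.07 (0.412) without heterozygous 4-week array 1. Simulated changes were recovered at 26.9% for 1.5-fold, 86.6% for 2-fold and 97.0% for 4-fold.

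Between 1 and 4 weeks after 10 cGy, averaged over genotypes, 9 genes rose and 0 fell by limma. They were Tox3, a chromatin-associated protein expressed in luminal epithelium, at 1.01 (SE 0.17), Dusp1 at 0.75 (SE 0.12), Pcdhb20, a protocadherin, at 0.69 (SE 0.11), Cep44, a centrosomal protein, at 0.64 (SE 0.10), and Klf11, a TGF-beta-inducible transcription factor, at 0.64 (SE 0.10). The others were Zfp963 at 0.61 (SE 0.10), Pramel12 at 0.58 (SE 0.10), Slc25a53, a mitochondrial carrier, at 0.49 (SE 0.08), and Sirt5, a mitochondrial deacylase, at 0.46 (SE 0.07). Other probe sets did not all agree, with a second Slc25a53 probe set at -0.22 (mean level 4.29 against 4.51), Sirt5 probe sets at 0.18 and 0.10, Pramel12 probe sets at 0.36 and 0.01, and Cep44 probe sets at 0.29 and 0.23. With the mean of probe sets Slc25a53 was at 0.14 (limma adjusted p = 0.527), Sirt5 at 0.25 (0.143), Cep44 at 0.39 (0.138) and Pramel12 at 0.32 (0.0699). In 5 of these genes, Tox3, Cep44, Klf11, Slc25a53 and Sirt5, all 6 arrays at 4 weeks lay above all 5 arrays at 1 week. Limma's adjusted p was 0.0488 for Pramel12 and 0.0403 for each of the others, and 2036 genes had an unadjusted p under 0.05. The median difference over all tested genes was itself 0.058 (median SE 0.12), 0.055 with median centring and 0.003 with quantile normalization. A shift shared by many genes may thus add to these counts and to their single direction, and its cause was not tested. The calls sat close to the threshold, since each gene was lost in 12 to 15 of the 17 fits without 1 array, and the count ran from 0, in 11 fits, to 64, without heterozygous 1-week array 1. With a stricter filter 0 genes passed limma (1438 at an unadjusted p under 0.05), with quantile normalization 0 (1724), with composition covariates 0 (2090) and without muscle-rich arrays 0 (1039). In the simulated data, recovery was 70.1% for 1.5-fold, 86.6% for 2-fold and 100% for 4-fold.

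Interferon genes were lower at 4 weeks than at 1 week. The type I interferon list was lower in 13 of 13 cases, with a mean of -0.41, a camera adjusted p = 0.000142 and an adjusted p = 0.865 with an estimated correlation, and Irf7, a regulator of interferon genes, was at -0.56 (SE 0.29). The interferon gamma list was lower in 11 of 13 cases, with a mean of -0.19, a camera adjusted p = 0.00110 and an adjusted p = 0.865 with an estimated correlation. Tap1, a peptide transporter, at -0.31 (SE 0.09) and Igtp at -0.47 (SE 0.15) passed when adjusted over the list alone and not over all genes. Most of that fall came from wild-type glands (8.47 to 8.15), against 8.03 to 7.97 in heterozygotes. Both lists passed camera in every fit without 1 array, with sizes that changed. The type I mean was -0.63 and -0.23 without wild-type 1-week array 1 and 2 (camera adjusted p = 0.00936 for the latter) and -0.27 without heterozygous 1-week array 1 (0.00710). The interferon gamma mean was -0.12 without wild-type 1-week array 1 (0.00838), and -0.05 (0.0330) and -0.32 without heterozygous 1-week array 1 and 2. Cholesterol synthesis genes were higher in 11 of 11 cases, with a mean of 0.29, a camera adjusted p = 0.0306 and an adjusted p = 0.865 with an estimated correlation. Of these, Hmgcs1 at 0.50 (SE 0.15), Fdft1 at 0.37 (SE 0.11) and 1 more gene passed when adjusted over the list alone. That call was lost without heterozygous 1-week array 2 (0.22, adjusted p = 0.0847), heterozygous 4-week array 3 (0.18, 0.183) or wild-type 4-week array 1 (0.29, 0.0746). The lymph-node list mean was 6.83 ± 2.38 and 5.31 ± 0.05 at 1 week (wild-type, heterozygous) and 5.37 ± 0.48 and 5.63 ± 0.29 at 4 weeks.

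The difference between genotypes in the response at 1 week was tested as an interaction. By limma 0 genes passed, with 395 at an unadjusted p under 0.05, and Cdkn1a was at -0.76 (SE 0.21). MHC class II genes were at a negative interaction in 9 of 9 cases, with a mean of -0.80, a camera adjusted p = 4.38e-06 and an adjusted p = 0.412 with an estimated correlation, meaning a more positive change in wild-type than in heterozygous glands. H2-DMa was at -0.99 (SE 0.33) and H2-Ab1 at -0.96 (SE 0.35). Macrophage genes were at a mean of -0.70 (13 of 14 negative), with a camera adjusted p = 0.000157 and an adjusted p = 0.698 with an estimated correlation. Interferon gamma genes were at a mean of -0.38 (12 of 13 negative), with a camera adjusted p = 5.45e-05 and an adjusted p = 0.412 with an estimated correlation. These 3 of the 10 lists past camera held in every fit without 1 array, with 0 members past limma over all genes or when adjusted over the list alone and 3, 1 and 3 members at an unadjusted p under 0.05. The macrophage mean was -0.42 without wild-type 1-week array 2 (camera adjusted p = 0.0149) and -0.40 without heterozygous 1-week array 2 (0.0212). The interferon gamma mean was -0.24 without wild-type sham array 1 (0.00288), and -0.645 and -0.115 (0.0155) without heterozygous 1-week array 1 and 2. Lymph-node genes moved the same way, at a mean of -1.74 (-0.41 without wild-type 1-week array 1 and -1.05 without heterozygous sham array 1), and without the 3 lymph-node-rich arrays the interferon gamma mean was -0.05 (camera adjusted p = 0.194). Without heterozygous 1-week array 1, 3 genes passed limma, in a fit that leaves 1 array in that group and takes the spread from other groups alone. Simulated interactions were recovered at 6.0% for 1.5-fold, 44.8% for 2-fold and 89.4% for 4-fold.

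None of the fixed genes Cdkn1a, Esr1, Pgr, Krt8, Krt5 and Mki67 passed limma in any of the 9 gland comparisons. At 4 weeks the interaction gave 0 genes by limma, with 231 at an unadjusted p under 0.05. Dusp1 was at 1.05 (SE 0.23). Luminal epithelium genes were at a negative interaction in 13 of 14 cases, with a mean of -0.40, a camera adjusted p = 2.68e-05 and an adjusted p = 0.754 with an estimated correlation. Krt19 was at -1.13 (SE 0.35) and Cldn4 at -1.02 (SE 0.35). Without heterozygous sham array 2 the mean was -0.26 (camera adjusted p = 0.0846), and without wild-type sham array 3 it was -0.60. Proliferation genes were negative in 23 of 23 cases, with a mean of -0.88, a camera adjusted p = 4.47e-06 and an adjusted p = 0.870 with an estimated correlation. Without wild-type sham array 2 that mean was -0.33 (0.204), without heterozygous 4-week array 1 it was -0.43 (0.0558), and without the 4 muscle-rich arrays, with wild-type sham array 1 alone, it was 0.46 (0.139). It was -1.39 without wild-type sham array 1, -0.57 without wild-type 4-week array 3 and -0.47 without heterozygous sham array 3. No member of either list passed limma over all genes or when adjusted over the list alone, with 3 luminal and 0 proliferation genes at an unadjusted p under 0.05, and none of the 6 lists past camera held in every fit without 1 array. Simulated interactions were recovered at 19.4% for 1.5-fold, 46.3% for 2-fold and 86.4% for 4-fold.

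Tumours in irradiated wild-type hosts, compared with sham wild-type hosts, had higher interferon gamma genes and lower endothelial genes. The interferon gamma list was higher in 12 of 12 cases, with a mean of 0.41, a camera adjusted p = 0.0229 and an adjusted p = 0.857 with an estimated correlation. Cxcl9, a chemokine that attracts T cells, was at 0.98 (SE 0.49). MHC class II genes were higher in 9 of 9 cases, with a mean of 0.31, a camera adjusted p = 0.0327 and an adjusted p = 0.857 with an estimated correlation. Endothelial genes were lower in 12 of 12 cases, with a mean of -0.48, a camera adjusted p = 0.0229 and an adjusted p = 0.857 with an estimated correlation, and Lyve1, a lymphatic marker, was at -1.76 (SE 0.59). Tumour 5 of the sham wild-type group had an endothelial mean of 11.34, and without it the difference was 0.01 (camera adjusted p = 0.835). That call was also lost without sham tumour 4 (-0.45, 0.0563) or irradiated tumour 16 (-0.46, 0.0571), and with the doubtful tumour moved to sham (-0.37, 0.0916). The interferon gamma call was lost without irradiated tumour 16 (0.33, 0.0571) or sham tumour 1 (0.33, 0.0618) or 8 (0.36, 0.0638), and the MHC class II call in 13 of the 48 fits without 1 tumour and with the doubtful tumour moved to sham (0.23, 0.119). Of single genes 0 passed limma (smallest adjusted p = 0.319), with 887 at an unadjusted p under 0.05, and Hmox1, heme oxygenase, was at -1.55 (SE 0.37). Members of these lists passed neither over all genes nor when adjusted over the list alone, with 1 endothelial gene at an unadjusted p under 0.05. Simulated changes were recovered at 50.7% for 1.5-fold, 65.7% for 2-fold and 97.0% for 4-fold.

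Tumours in irradiated heterozygous hosts, compared with sham heterozygous hosts, had higher adipocyte genes and lower proliferation genes. Adipocyte genes were higher in 11 of 12 cases, with a mean of 0.68, a camera adjusted p = 4.49e-06 and an adjusted p = 0.419 with an estimated correlation. Plin4, a lipid droplet protein, was at 1.36 (SE 0.46) and Adipoq, the hormone adiponectin, at 1.86 (SE 0.88). Proliferation genes were lower in 22 of 23 cases, with a mean of -0.33, a camera adjusted p = 4.54e-07 and an adjusted p = 0.461 with an estimated correlation. Mcm3, a helicase subunit, was at -0.56 (SE 0.20) and Cdc20, an activator of mitotic exit, at -0.61 (SE 0.24). Both calls held in each of the 48 fits without 1 tumour, unlike the other 10 of the 12 lists past camera. Skeletal muscle genes were also higher, at a mean of 0.68 with a camera adjusted p = 0.0122 (adjusted p = 0.599 with an estimated correlation), a call lost without irradiated tumour 9 (0.34, 0.144) or 17 (0.27, 0.239). Of single genes 0 passed limma, with 505 at an unadjusted p under 0.05. Over all genes and when adjusted over the list alone 0 members of these lists passed, with 4 adipocyte, 2 proliferation and 0 muscle genes at an unadjusted p under 0.05. In the simulated data, recovery was 26.9% for 1.5-fold, 79.1% for 2-fold and 92.4% for 4-fold.

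Among tumours of sham hosts, those in heterozygous hosts had higher basal genes than those in wild-type hosts. Of 13 basal and myoepithelial genes 11 were higher, with a mean of 1.20, a camera adjusted p = 0.000119 and an adjusted p = 0.684 with an estimated correlation. The list mean was 8.85 ± 1.27 (n = 6) against 7.64 ± 0.65 (n = 9). Col17a1, a hemidesmosomal collagen, at 2.98 (SE 0.97), and Trp63, the regulator of basal identity, at 2.33 (SE 0.82), passed when adjusted over the list alone and not over all genes. Krt5, a basal keratin, was at 2.07 (SE 0.81). The call held in every fit without 1 tumour. Squamous differentiation genes were higher in 8 of 8 cases, with a mean of 0.79, a camera adjusted p = 0.0349 and an adjusted p = 0.684 with an estimated correlation. Krt6a, a keratin of stratified epithelium, was at 2.50 (SE 1.09). That call was lost without heterozygous-host tumour 2 (0.46, 0.140) or 5 (0.62, 0.158) or wild-type-host tumour 6 (0.69, 0.114) or 9 (0.78, 0.0564). Tgfb1 was at -0.94 (SE 0.31), with a limma adjusted p = 0.872. Of single genes 0 passed limma, with 676 at an unadjusted p under 0.05, and Flrt1, a membrane protein of fibroblast growth factor signalling, came closest at 0.64 (SE 0.13, adjusted p = 0.123). Without heterozygous-host tumour 4, 1 gene passed. Simulated changes were recovered at 28.4% for 1.5-fold, 65.7% for 2-fold and 83.3% for 4-fold.

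Among tumours of irradiated hosts, Dcstamp, a membrane protein needed for the fusion of osteoclasts and macrophages, was higher in heterozygous hosts by 1.72 (SE 0.31). It averaged 7.03 ± 1.02 (n = 10) in heterozygous and 5.31 ± 0.58 (n = 23) in wild-type hosts, and 4 of the 10 tumours of heterozygous hosts lay above all 23 of wild-type hosts, with all 10 above their median. Its limma adjusted p was 0.0166, it was the only gene past the threshold, and 716 genes had an unadjusted p under 0.05. It missed the threshold without heterozygous-host tumour 9 (adjusted p = 0.0867), 11 (0.113), 12 (0.0769) or 18 (0.0562). Jchain, the joining chain of secreted antibodies, was at 2.34 (SE 0.59, adjusted p = 0.456) and Agtr1a, an angiotensin receptor, at 2.08 (SE 0.50), neither passing limma. In the simulated data, recovery was 55.2% for 1.5-fold, 74.6% for 2-fold and 97.0% for 4-fold.

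In the same comparison 4 lists passed camera in every fit without 1 tumour, out of 8 that passed. Endothelial genes were higher in heterozygous hosts in 12 of 12 cases, with a mean of 0.66, a camera adjusted p = 1.21e-05 and an adjusted p = 0.579 with an estimated correlation. Vwf, von Willebrand factor, was at 0.98 (SE 0.33). Adipocyte genes were higher in 12 of 12 cases, with a mean of 0.51, a camera adjusted p = 1.21e-05 and an adjusted p = 0.494 with an estimated correlation. Hormone-sensing luminal genes were higher in 6 of 7 cases, with a mean of 0.92, a camera adjusted p = 0.000531 and an adjusted p = 0.494 with an estimated correlation. Proliferation genes were lower in 23 of 23 cases, with a mean of -0.18, a camera adjusted p = 0.000861 and an adjusted p = 0.673 with an estimated correlation. Leaving out heterozygous-host tumour 12 lowered the endothelial mean to 0.42 (camera adjusted p = 0.00351), and leaving out tumour 14 lowered the hormone-sensing mean to 0.54 (0.0193). Plin4, at 1.07 (SE 0.34), and Pgr, at 1.78 (SE 0.60), each passed when adjusted over the list alone and not over all genes. Basal genes were higher by a mean of 0.48, with a camera adjusted p = 0.0236 (adjusted p = 0.606 with an estimated correlation). Heterozygous-host tumour 9 had a basal mean of 11.08, and without it that difference was 0.17 (0.492), while without tumour 17 it was 0.45 (0.0516).

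**Figure D3:**
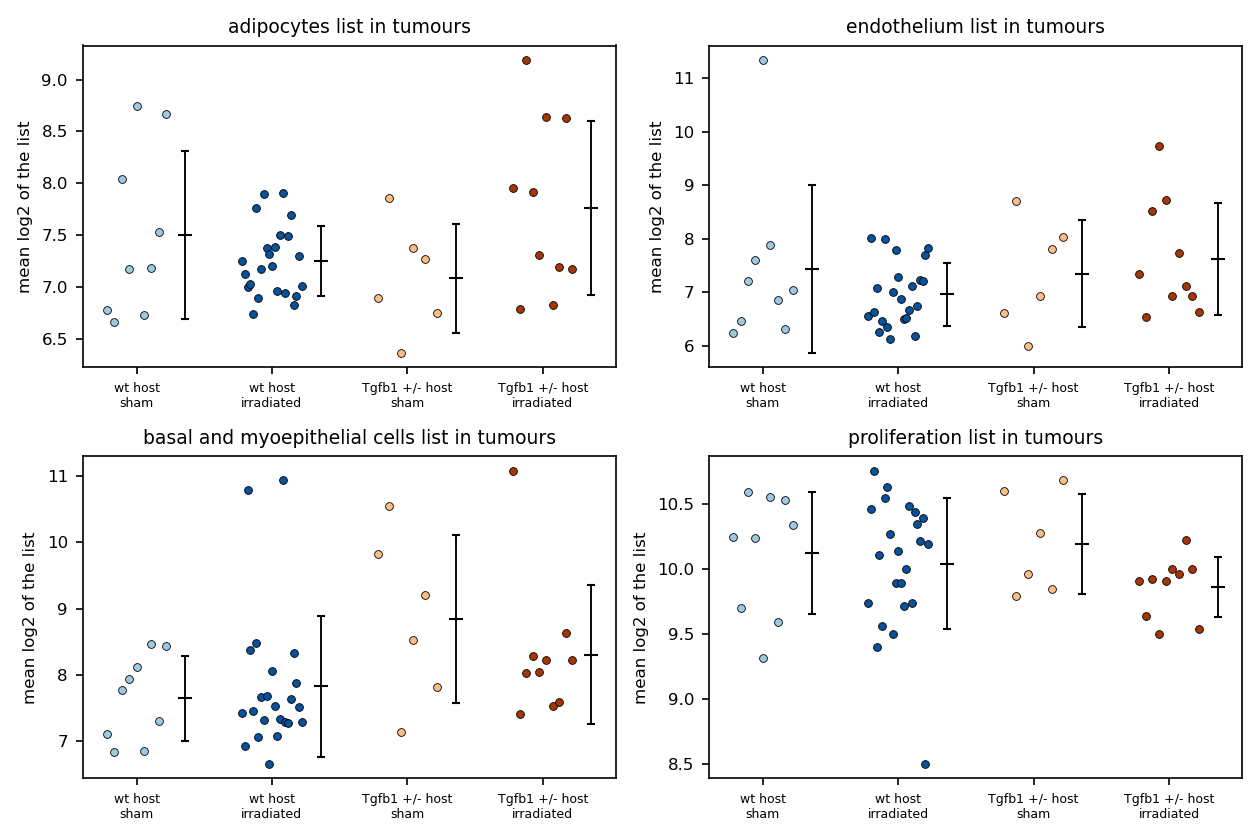
Mean log2 level of the adipocyte, endothelium, basal and myoepithelial, and proliferation lists in each tumour (points) by host group, with bars for the mean ± SD, wt being wild-type. Single tumours lie far from their groups, such as 11.34 for endothelium in a sham wild-type host and 11.08 for basal genes in an irradiated heterozygous host.

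The interaction of host radiation and host genotype tested whether the response of tumours differed between hosts. By limma 0 genes passed, with 617 at an unadjusted p under 0.05. Adipocyte genes had a positive interaction in 11 of 12 cases, with a mean of 0.93, a camera adjusted p = 1.69e-06 and an adjusted p = 0.330 with an estimated correlation. Plin4, at 1.82 (SE 0.58), passed when adjusted over the list alone, and Cidec, a lipid droplet protein of fat cells, was at 1.61 (SE 0.61). Adipocyte list means were 7.50 ± 0.81 and 7.25 ± 0.34 in sham and irradiated wild-type hosts and 7.08 ± 0.53 and 7.76 ± 0.84 in sham and irradiated heterozygous hosts. The call held in each of the 48 fits without 1 tumour. Endothelial genes were positive in 12 of 12 cases, with a mean of 0.75, a camera adjusted p = 0.00933 and an adjusted p = 0.963 with an estimated correlation. Without wild-type sham tumour 5 that mean was 0.26 (0.437), and the call was also lost without heterozygous sham tumour 1 (0.60, 0.0570) or 3 (0.48, 0.139) or heterozygous irradiated tumour 12 (0.51, 0.0702). Simulated interactions were recovered at 16.4% for 1.5-fold, 52.2% for 2-fold and 84.8% for 4-fold.

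**Figure D4:**
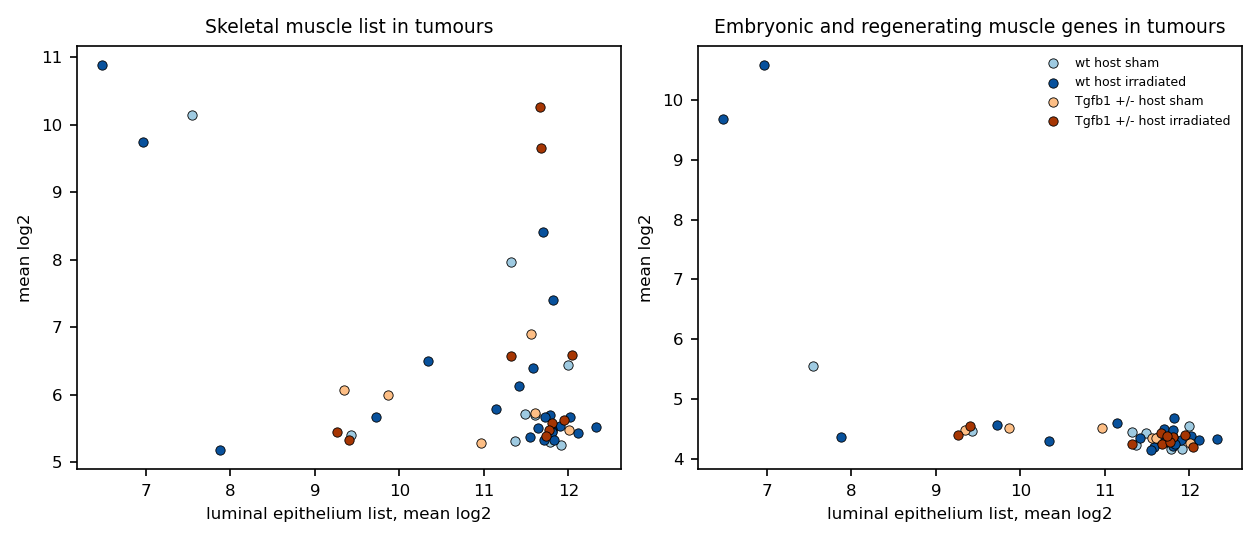
Mean log2 level of the skeletal muscle list (left) and of embryonic and regenerating muscle genes (right) against that of the luminal epithelium list, 1 point per tumour, coloured by host group, wt being wild-type. Embryonic muscle genes stand at 9.67 and 10.58 in a pair of tumours of irradiated wild-type hosts and at 4.69 or less in 45 of the tumours.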

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

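The 3 tests of the MHC class II pattern in this part were chosen after the result was seen, while the interaction tests, the test for single tumours far from their group and the splits of the arrays were planned. For 10 gene lists the radiation difference at 1 week differed between heterozygous and wild-type glands by camera's interaction test at its preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.412 to 0.728). More positive in heterozygotes were milk proteins (2.39, camera adjusted p = 3.28e-08), luminal progenitor and alveolar genes (0.42, 0.000123), skeletal muscle (3.03, 4.06e-06), hormone-sensing luminal genes (0.74, 0.00949) and brown adipocytes (0.63, 0.0484). Without heterozygous 1-week array 2 the milk interaction was 0.09 (0.372), the progenitor interaction 0.26 (0.0966) and the muscle interaction 1.77 (0.0739). A fit without either heterozygous 1-week array leaves 1 array in that group. Milk was at 4.69 without heterozygous 1-week array 1, and muscle at 4.89 without wild-type sham array 1, 1.45 without wild-type sham array 2 and 4.63 without wild-type 1-week array 3. The hormone-sensing call was lost in 5 and the brown adipocyte call in 9 of the 17 fits without 1 array, moving most to 0.47 without wild-type 1-week array 1 and to 0.39 without heterozygous sham array 2. More negative were MHC class II (-0.80, 4.38e-06), interferon gamma response (-0.38, 5.45e-05), macrophages (-0.70, 0.000157), B cells and lymph node (-1.74, 0.00949) and T and NK cells (-0.96, 0.00949). Without wild-type 1-week array 1 the lymph-node interaction was -0.41 (0.656) and the T and NK interaction -0.27 (0.614), and these calls were lost in 4 and 5 of the 17 fits, with -1.05 and -0.53 without heterozygous sham array 1. Values of interferon gamma and macrophages without single arrays are given above.

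At 4 weeks 6 lists differed between genotypes in the same way, by camera at its preset correlation and not with an estimated correlation (adjusted p = 0.563 to 0.870). They were luminal epithelium (-0.40, camera adjusted p = 2.68e-05), basal and myoepithelial cells (-0.28, 0.0184), proliferation (-0.88, 4.47e-06), adipocytes (0.22, 0.00589), neutrophils (0.48, 0.00133), and hypoxia and glycolysis (0.23, 0.00533). Calls were lost without heterozygous sham array 2 for luminal epithelium (-0.26, 0.0846; -0.60 without wild-type sham array 3), without wild-type 4-week array 3 for neutrophils (0.38, 0.128), and without heterozygous sham array 2 (0.15, 0.183) or wild-type sham array 3 (0.20, 0.0530) for hypoxia. Proliferation was lost without wild-type sham array 2 (-0.33, 0.204) or heterozygous 4-week array 1 (-0.43, 0.0558), with further values given above. The calls were lost for basal cells and adipocytes in 7 and 5 of the 17 fits, up to 0.252 without wild-type sham array 1 (-0.18) and 0.261 without heterozygous sham array 2 (0.095), with adipocytes at 0.365 without heterozygous sham array 1. In tumours 6 lists differed between host genotypes, again not with an estimated correlation (adjusted p = 0.330 to 0.963). They were adipocytes (0.93, camera adjusted p = 1.69e-06), brown adipocytes (0.77, 0.0497), skeletal muscle (0.80, 0.0284), endothelium (0.75, 0.00933), fatty acid synthesis (0.28, 0.0284) and proliferation (-0.25, 0.00933). Of these, adipocytes held in each of the 48 fits without 1 tumour. Brown adipocytes were lost in 29 of them, skeletal muscle in 8 (up to 0.296, without wild-type sham tumour 6), fatty acid synthesis in 6 (up to 0.0813, without wild-type sham tumour 9), and endothelium and proliferation in 4 each (up to 0.437 without wild-type sham tumour 5 and 0.124 without heterozygous sham tumour 6). Muscle was at 0.33 without wild-type sham tumour 6, 0.46 without heterozygous irradiated tumour 9 and 0.39 without tumour 17 of that group. Fatty acid synthesis was at 0.18 and proliferation at -0.153 without heterozygous sham tumour 6, proliferation at -0.149 and endothelium at 0.26 without wild-type sham tumour 5, and endothelium at 0.48 without heterozygous sham tumour 3.

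MHC class II genes were higher in wild-type glands 1 week after 10 cGy by a mean of 0.59, and the change in heterozygotes differed from it, both by camera at its preset correlation and neither with an estimated correlation (adjusted p = 0.572 and 0.412). Leaving out wild-type 1-week array 1 lowered the mean to 0.34 (camera adjusted p = 0.00610). A lower share of epithelium would raise fibroblast, endothelial and adipocyte genes alike. The class II list stood above the mean of those 3 lists by 0.63 (SE 0.28). With 3 arrays a side, that gap does not exclude this cause. Skeletal muscle in the sham arrays was argued against as the whole cause, since with the muscle list as a covariate the difference was 0.49 (camera adjusted p = 6.56e-06). Residual lymph node, rich in class II-positive B cells, stays open, because without the 3 lymph-node-rich arrays the difference was 0.44 (camera adjusted p = 0.00333), between the bounds set for and against that cause. An effect of radiation on resident immune cells may also be present, as a hypothesis that these bulk arrays do not test.

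In tumours, 7 of 84 tests for a sample far from its group passed, where chance gives about 4.2. The group of 23 tumours of irradiated wild-type hosts was left out of these tests because of its size, so they say nothing about it. The tests overlapped, since Tgfb1 and Krt5 are also members of tested lists. In the sham wild-type group tumour 5 stood apart in endothelial genes (11.34, next tumour 7.87), TGF-beta pathway components (9.76, next 9.49) and Tgfb1 (11.33, next 9.49), and tumour 7 in Dcstamp (7.04, next 5.27). In the irradiated heterozygous group tumour 9 stood apart in basal genes (11.08, next 8.63) and Krt5 (10.07, next 8.04), and tumour 12 in Tgfb1 (9.29, next 8.69).

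Other splits of the same arrays were refitted with limma to count how often as many genes passed. For the genotype average 3 of 100 splits, the real one included, gave at least the 6 genes found, so a count that high was uncommon among splits. The highest other split gave 121 genes, which points to a structure in the glands apart from genotype that was not identified here. For the change from 1 to 4 weeks 1 of 100 splits, the real one, gave the 9 genes found, and the highest other gave 1. Both shares treat the glands as independent, which the labels do not state, and were not adjusted over the comparisons split. The splits alone therefore do not exclude chance, and the 9 calls sat close to the threshold, as given above. For tumours of irradiated hosts 5 of 100 splits gave at least the 1 gene found, the highest other gave 5, and chance was not excluded. With 0 genes found, all 100 splits gave as many whatever the data, so these counts decide nothing, for the gland interaction at 4 weeks (highest other 24), irradiated against sham wild-type hosts (39), irradiated against sham heterozygous hosts (12), heterozygous against wild-type sham hosts (371) and the tumour interaction (3). At an unadjusted p under 0.05 at least as many genes as in the real grouping were found in 84, 26, 44, 50 and 43 of the 100 splits of these comparisons. The split with 371 genes points to a structure among those tumours apart from host genotype, and what it separates was not identified here. Comparisons of 3 glands with 3 allow 10 splits, too few for a share under 0.05. For heterozygotes at 4 weeks 1 of 10 splits gave the 2 genes found (highest other 0). With 0 found, 10 of 10 gave as many, again whatever the data, for wild-type glands at 1 week (highest other 57) and at 4 weeks (0) and for sham genotype (0).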

How the results depend on the processing

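Fits chosen after the results were seen are listed above. Counts of genes past limma's threshold are given with the number at an unadjusted p under 0.05 in parentheses. The genotype average, 6 genes, became 12 (2107) without the filter, 11 (2086) with a replicate block, 1 (935) without muscle-rich arrays, which was none of the 6, and 0 (1707) without lymph-node-rich arrays. The time comparison, 9 genes, became 0 with the stricter filter (1438), quantile normalization (1724), composition covariates (2090), the replicate block (2147) and muscle-rich arrays left out (1039), 3 (1927) with the mean of probe sets, 1 (1983) with the compared groups only and 1 (1971) with a muscle covariate. Heterozygotes at 4 weeks, 2 genes, became 14 (935) with array weights, 4 (765) without muscle-rich arrays, 1 (702) with the mean of probe sets, and 0 with composition covariates (1042), the compared groups only (788), the replicate block (725) and lymph-node-rich arrays left out (554). Wild-type at 1 week, 0 genes, became 1 (1187) without lymph-node-rich arrays. Tumours of irradiated hosts, 1 gene, became 2 without the filter (1174) or with array weights (1314), and 0 (520) with the stricter filter, under which Dcstamp was not tested. Directions split as 8 higher and 3 lower without the filter and 10 and 1 with array weights for time, against 9 and 0. For heterozygotes at 4 weeks they split as 4 and 10 with array weights, against 1 and 1. For genotype, against 3 and 3, they split as 9 and 3 without the filter, 5 and 2 with the mean of probe sets, 5 and 3 with array weights, 6 and 5 with the replicate block, and 4 and 2 with quantile normalization, composition covariates or a muscle covariate. Tumours of irradiated hosts split as 1 and 1 with array weights, against 1 and 0. Over fits leaving out 1 array, counts ran from 0 to 15 for heterozygotes at 1 week, 0 to 4 for heterozygotes at 4 weeks (0 in 9 fits), 0 to 2 for sham genotype (2 without heterozygous sham array 3), 3 to 15 for the genotype average, 0 to 64 for time (0 in 11 fits), 0 to 3 for the interaction at 1 week, and 0 to 1 for tumours of sham hosts (1 without heterozygous-host tumour 4) and of irradiated hosts (0 without heterozygous-host tumour 9, 11 or 12). List calls ran from 60 to 86 in glands, against 67, and from 29 to 46 in tumours, against 36, and were 0 with an estimated correlation and 0 with the rotation test in both tissues. Without muscle-rich arrays the sign turned for wild-type immediate early genes at 1 week (0.004, camera adjusted p = 0.814), wild-type at 4 weeks muscle (1.30), DNA repair (-0.33) and proliferation (-0.68), sham genotype muscle (1.08), DNA repair (-0.19) and proliferation (-0.35), genotype average muscle (0.78) and interaction proliferation at 4 weeks (0.46), with the cause not tested beyond the 4 arrays removed. All of these comparisons use the wild-type sham group, of which that fit keeps array 1 alone, so the turned signs rest on a single array and their spread on the other groups. Leaving out 1 array turned wild-type muscle at 4 weeks (-3.05 to 0.40), wild-type DNA repair at 4 weeks (-0.007 to 0.46), hormone-sensing genes in heterozygotes at 4 weeks (-0.29 to 0.26), milk proteins in heterozygotes at 1 week (-1.02 to 3.58) and endothelium in tumours of wild-type hosts (-0.63 to 0.012). Whether repeat numbers pair glands is not settled. Same-numbered glands had a median correlation of deviations of 0.12 in wild-type (5 of 9 pairs over 0.1) and 0.14 in heterozygotes (5 of 7). Differently numbered glands were at -0.07 and -0.12. Same-numbered tumours were at -0.03 (4 of 9) and others at 0.03. An array correlated best with its own number in 4 of 9, 6 of 8 and 4 of 18 cases, and tumours of heterozygous hosts share no numbers, so the replicate block was not run for them alone. The block gave 80 gland and 33 tumour list calls. Among 4-week against sham comparisons and their interaction, where the numbers may pair the glands, it ended the calls of Dusp1 and Tuba8 and no call of a list. With a muscle covariate 51 gland lists passed, without muscle-rich arrays 80, and without lymph-node-rich arrays 94. The doubtful tumour changed no count of genes. For other listed results the cause of a change was not tested.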

Other observations

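The test of the 2 muscle-rich tumours of irradiated wild-type hosts in this part was chosen after the result was seen, and the other tests were set before it. Igha and Jchain were picked after their values were seen, and no list of immunoglobulin genes was tested. Igha, the heavy chain of IgA, was at 1.81 in heterozygous glands averaged over conditions, with a limma adjusted p = 0.0570, and at 2.24 in tumours of irradiated heterozygous against irradiated wild-type hosts, neither passing. Jchain, which joins IgA and IgM chains, averaged 8.22 ± 1.59 (n = 10) in tumours of irradiated heterozygous hosts, 5.88 ± 1.51 (n = 23) in irradiated wild-type, 6.85 ± 2.36 (n = 6) in sham heterozygous and 6.18 ± 1.14 (n = 9) in sham wild-type hosts. Pgr varied widely within tumour groups, from 3.95 to 12.37 in irradiated heterozygous hosts and from 3.84 to 7.62 in irradiated wild-type hosts.

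The leading axis of variation in glands carried 21.0% of the variance and ran along skeletal muscle genes such as Myh1, Myh4, Acta1 and Ckm. The next axis, with 16.5%, set cell-cycle genes such as Aspm and Kif11 and the milk gene Wap against lymphocyte genes such as Cd3d, Cd22 and Ccr7. In tumours the leading axis, with 27.1%, set epithelial genes such as Cldn3, Cldn7 and Ehf against mesenchymal genes such as S100a4, Grem1 and Pdpn.

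Tyw5 and Maip1, both higher in heterozygous glands, lie next to each other in the order of measured genes. A chromosomal segment around Tyw5 and Maip1 that differs between the littermates stays open, since 7 of the 40 nearest measured genes had an unadjusted p under 0.05 for genotype, between the median of 5 and the 95th percentile of 9 in 12119 windows across the genome, and 20.1% of windows had at least as many. That count took no account of direction and could miss a short segment. The measured gene directly beside Tyw5, an unnamed Riken gene, was also higher, at 0.51 (limma unadjusted p = 0.000641). Beyond it Rftn2 was at -0.23, and Spats2l, beside Maip1, was at -0.13. The test set for a passenger segment around Tgfb1 counted 3 such genes among its 40 nearest, but neither Tyw5 nor Maip1 is among them, so whatever that count had been it could not bear on the pair. A shared regulatory effect of lower Tgfb1 may account for the pair, as an untested hypothesis.

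Some tumours had high skeletal muscle genes and low luminal epithelium genes, namely tumours 2 and 23 of irradiated wild-type hosts (muscle 9.74 and 10.89, epithelium 6.96 and 6.48) and tumour 6 of sham wild-type hosts (10.15 and 7.54). Adult muscle caught in the tumour piece would leave genes of embryonic and regenerating muscle at the level of other tumours, of which the highest was 4.69. In the first 2 tumours those genes were at 10.58 and 9.67, at least 4.12 above every other tumour including tumour 6 at 5.55, with Myog, a regulator of muscle differentiation, at 12.72 and 11.82, so adult muscle alone was argued against there. Over all 3 tumours the smallest gap was 0.87, in tumour 6, under the 1 log2 unit set in advance, so adult muscle cannot be told apart from a myogenic programme in that tumour. A myogenic differentiation of some p53-null tumours is a hypothesis from these data, and tumours 9 and 17 of irradiated heterozygous hosts had muscle means of 9.65 and 10.27 with embryonic muscle genes at 4.25 and 4.44.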
